A study of Homo sapiens with 4 samples.

How the data were processed

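RNA of SK-LC-7 cells transfected with pre-miR-195, pre-miR-30d, pre-miR-182-3p or a negative control precursor (NC) was compared on 4 two-colour arrays with 41000 distinct probes, 1 array per group. Per the labels' protocols, cDNA was made from 100 ng of total RNA with an oligo-dT primer, the transfected cells were labelled with Cy5 and a mixture of 20 cell lines with Cy3, so that the ratio runs as transfected cells over reference on every array and no dyes were swapped. Groups were taken from the source names in the labels. The series design names miR-30d, miR-195 and the control, with harvest at 72 hours; it does not name miR-182-3p. The design also mentions a network of genes whose list was not used here.

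Per the file headers, images were read with Agilent Feature Extraction 10.7.1.1 with a 2-channel protocol, and the deposited spot values are intensities: the median brightness of each spot and of its local background in each channel, the background-subtracted signal, and a processed signal corrected for background and dye by that program. The deposited files also give a log10 ratio of Cy5 over Cy3 per spot. The authors' value table of the series was found to hold log2 values. For 100% of probes with 1 spot it equalled log2 of the processed Cy5 over the processed Cy3 signal of the same array within 1e-05, so that its scale and direction are known and it was not centred. The medians of its columns were -0.0052, -0.055, -0.070 and -0.11 for miR-195, miR-30d, miR-182-3p and NC.

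From the intensities, background was corrected in each channel with normexp (offset 50) and log2 ratios were normalised within each array by loess, with limma 3.58.1 in R 4.3.3. The mean spot signal named in the design fixed before the data were examined is not among the columns used here, so the median spot signal took its place. Control spots had weight 0 in the loess fit, and control and outlier spots were left out afterwards. Spots whose local background Feature Extraction had marked as non-uniform were left out of the normexp fit and of averages, a choice made after seeing the data. There were 36 such spots on the miR-30d array. Keeping them raised the fitted SD of its Cy5 background from 1.35 to 158. Each array held 43376 spots apart from controls. The median Cy5 brightness was 285, 264, 249 and 271.5 and the median Cy3 brightness 169.5, 162.5, 161 and 176 for miR-195, miR-30d, miR-182-3p and NC. The arrays' log2 ratios correlated with r between 0.88 and 0.96 over all probes. Probes printed 10 times had a median SD of the log2 ratio of 0.043 to 0.048 between spots.

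The files name probes by accession. Accessions without versions were matched to a RefSeq table of the assembly GRCh38.p14, of which only names were used, since the array design is annotated on hg18. Of the probes, 24789 had 1 symbol and 16211 none, and 96.7% of the 25292 probes with a RefSeq messenger RNA accession were matched. This gave 16958 genes, 16938 with values on all arrays. A gene was represented by its probe of highest mean intensity. Of the 4512 to 4519 genes with several measured probes, probes lay at least 1.5-fold on opposite sides in 5 genes with miR-195, 0 with miR-30d and 4 with miR-182-3p. A gene counted as measured in a comparison when its probe was well above background and not saturated in Cy5 on both arrays. A gene measured on 1 side only was given as a bound: the bright array's Cy5 value against the higher of the lowest signal well above background and the dim probe's own signal, after loess and Aquantile normalisation. Such bounds are open to dye bias.

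With 1 array per group there are no residual degrees of freedom, so no test was run. The change is the difference of log2(Cy5/Cy3) between a mimic and NC, or between mimics, and the thresholds are 2-fold for counts of genes and 1.5-fold for members of lists. The number of arrays limits the precision. Technical spread was taken from the Cy3 channel, quantile normalised between arrays. The 25 gene lists were fixed before the data were examined, from general knowledge, and cover published targets of the 3 microRNA families, cell cycle, stress, lipid, inflammatory and lineage genes, and markers of leukocytes and fibroblasts. A list needed 5 measured members, and its median was ranked among 10000 random lists matched in 20 bins of mean intensity (Python 3.11.15, numpy 2.4.6, pandas 2.3.3). Overlaps with the shared control were set against 100 simulations of unchanged mimics that hold technical spread only.

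The genes named were chosen by a rule fixed at the same time. Per mimic it takes the 12 largest decreases and 12 largest increases among measured genes with a proper symbol, the same direction under every background and normalisation alternative and against the mean of the other 2 mimics, and a Cy3 difference under 1 log2 unit. It adds up to 4 members of each list that stood apart, up to 8 members of each mimic's own published target list, and NKX2-1 and EZH2. A few genes that the rule takes are not reported here. Genes outside the rule are said to be so, or are single members that a count refers to. The published miR-182-5p list stood in for miR-182-3p.

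The alternatives were no background subtraction, Agilent's processed signals, the deposited value table, median centring in place of loess, the Cy5 channel alone, no filter on dim probes, a filter on Cy3 as well, the mean over probes, the mean of the other 2 mimics as control, a 1.5-fold threshold and a normexp fit on all spots. The last became an alternative when flagged spots were left out after seeing the data. The design had named no such exclusion, so the fit on all spots is the closest to the plan. A planned search for seed matches in 3' untranslated regions was not run, since no transcript sequence was used here. The procedure was tested on simulated data built for miR-30d against NC, with 200 of 28317 probes changed. It placed 2% of probes changed 1.5-fold past the 2-fold threshold, 20% of those changed 2-fold, 98% of those changed 3-fold and 98% of those changed 4-fold, against 0.42% of unchanged probes. Changes planted at 4-fold were recovered as 3.48-fold, since the offset compresses ratios. Among 200 simulated lists of 20 genes, 8% stood apart with no shift and 100% with a shift of -0.3, so a list just past the limit carries little weight. The simulated noise was independent between probes, whereas genes of a real list can vary together between cultures. Real lists may therefore stand apart without an effect of the mimic more often than 8%.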

Results

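Gene expression was measured in SK-LC-7, a human lung adenocarcinoma cell line, after transfection with a synthetic precursor of miR-195, miR-30d or miR-182-3p or with a negative control precursor (NC). Such precursors enter the microRNA pathway and raise the amount of the mature microRNA, which lowers messenger RNAs that carry matches to its seed. The series design states the aim for miR-30d and miR-195: to see how expression changed in cells harvested 72 hours after transfection. It names no aim for miR-182-3p, the strand opposite miR-182-5p in the same hairpin, and gives no time for it. Each of the 4 groups had 1 array, and all arrays lay on 1 slide. The Cy5 channel held RNA of the transfected cells and the Cy3 channel RNA of a mixture of 20 cell lines, the same reference on every array. Cy5 signal was well above background for 71.1% of spots with miR-195, 70.5% with miR-30d, 72.0% with miR-182-3p and 70.1% with NC, and no spot was saturated.

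No group had a replicate, so none of the differences below has a replicate check, no p-value is given, and "higher" and "lower" describe these arrays. All gene values are log2 changes of the Cy5/Cy3 ratio against the NC array unless stated otherwise. Comparisons against the mean of the other 2 mimics use the same mimic array as those against NC. They are no independent check, and genes picked for a large change tend to keep their sign by construction. Part of the measurement noise could be seen from the reference channel. Between the same pairs of arrays, the Cy3 signal of 9, 11 and 12 genes differed at least 2-fold for miR-195, miR-30d and miR-182-3p, whereas the Cy5 signal alone differed that much for 571, 214 and 638 genes. The SD of the Cy3 difference over genes was 0.11, 0.13 and 0.12 on the log2 scale. This covers the array and the Cy3 channel, and not the Cy5 labelling of each sample or the variation between cultures. The ratio carries the noise of both channels. In the data simulated for miR-30d, 0.42% of unchanged probes passed 2-fold, where 0.58% of measured genes were lower and 0.58% higher with miR-30d. A gene list is said to stand apart when its median change lay in the outermost 2.5% at either end of 10000 random lists of the same size and mean expression. Random lists are drawn gene by gene, so they do not allow for members of a list that vary together between single cultures.

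**Figure D1:**
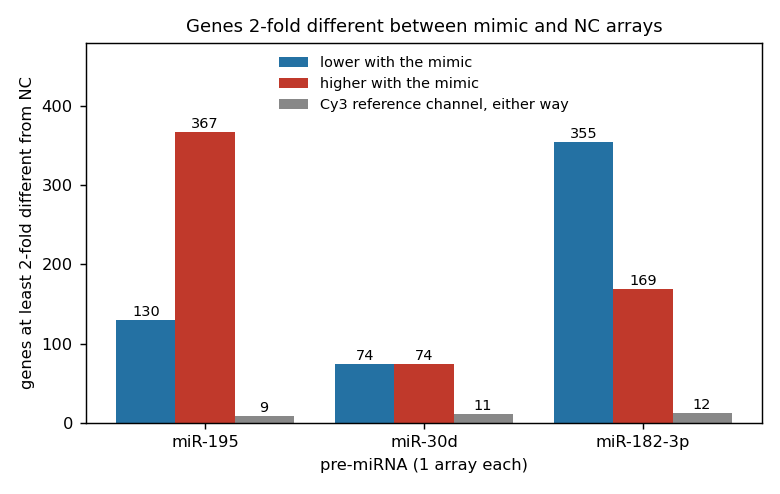
Number of genes (vertical axis) at least 2-fold lower (blue) or higher (red) than NC with each pre-miRNA, 1 array each, beside the number for which the Cy3 reference channel alone differed at least 2-fold in either direction (grey). The reference channel gave 9, 11 and 12 genes, against 130 lower and 367 higher with miR-195, 74 and 74 with miR-30d, and 355 and 169 with miR-182-3p. The lower and higher counts are of Cy5/Cy3 ratios, which carry the noise of both channels, so the grey bars are not their noise level.

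With miR-195, published targets of the family of miR-15, miR-16 and miR-195 were lower, as were cell cycle and cholesterol synthesis genes, while inflammatory and interferon-stimulated genes were higher. Of 12830 genes measured on both arrays, 130 were at least 2-fold lower and 367 at least 2-fold higher. The 34 published targets had a median change of -0.35, below all 10000 random lists. Of them, 14 were at least 1.5-fold lower and 1, TP53INP1, higher (1.66). The other 19 changed less, among them BCL2 (-0.03) and CCNE1 (0.15), and 6 of the 34 were above 0. ARL2, a small GTPase that takes part in tubulin folding, was at -2.15, ANLN, an actin-binding protein of the cleavage furrow, at -1.51, and CDC25A, a phosphatase that activates cyclin-dependent kinases, at -1.47. CDK4 (-0.99) and its partner CCND3 (-0.98), the scaffold protein CARD10 (-0.94), the checkpoint kinase CHEK1 (-0.93) and the mitotic kinesin KIF23 (-0.84) were also lower. Some were lower with another mimic too: ANLN (-0.79) and CDK4 (-0.56) with miR-30d, and ARL2 (-0.86) and CHEK1 (-0.72) with miR-182-3p. In contrast, CCND3 was higher with miR-30d (0.74) and miR-182-3p (0.57). The same list had a median of 0.03 with miR-30d (percentile 66.5) and 0.08 with miR-182-3p (percentile 86.1). In the reference channel the list differed by a median of -0.0047 between the miR-195 and NC arrays.

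Among proliferation genes, 34 of 35 mitotic genes were below 0 with miR-195, with a median of -0.32, and 4 were at least 1.5-fold lower: ANLN, KIF23, NUF2 (-0.75) and BUB1 (-0.71). The G1/S list, which mixes cyclins, kinases and E2F factors with kinase inhibitors and pocket proteins that restrain them, had a median of -0.31 over 23 genes. Of these, 6 were at least 1.5-fold lower and 4 higher, the latter being the pocket protein RBL2 (0.84), the inhibitors CDKN1A (0.76) and CDKN1B (0.61), and E2F2 (0.61). E2F7, a repressor of the E2F family, was at -1.09. The 33 DNA replication genes had a median of -0.15 (percentile 1.22), with 4 lower and 1 higher by 1.5-fold, among them RFC3 (-0.84, with a second probe at 0.02), MCM7 (-0.71), RRM2 (-0.66) and GINS1 (-0.61), with UHRF1 at 1.20. The first 2 lists hold members of the target list as well. Of the 6 lower G1/S genes, all but E2F7 (CDC25A, CDK4, CCND3, CDK6 and CCND1) are in it. Of the lower mitotic genes, ANLN and KIF23 are. The G1/S decreases of that size are thus largely those of the target list. Against the mean of the other 2 mimics, the mitotic list kept its side at -0.12 (percentile 2.25), whereas the G1/S list was at -0.03 (percentile 20.8) and the replication list at 0.03 (percentile 45.5). The replication list also did not stand apart with median centring (-0.17).

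The largest shift of any list was that of the NF-kB inflammatory genes with miR-195. All 16 measured members were above 0, 14 of them at least 1.5-fold, with a median of 1.13. The neutrophil chemokines CXCL1 (1.86) and CXCL2 (1.59), the TNF family ligand LTB (1.85) and the chemokine CCL20 (1.54) were the highest. Interferon-stimulated genes had a median of 0.39 over 22 members (percentile 99.96), and 9 were at least 1.5-fold higher, including CXCL10 (1.47), OASL (1.45), IFIT2 (1.32) and IFI6 (1.17). Against the mean of the other 2 mimics the medians were 0.88 for the NF-kB list and 0.34 for the interferon list (percentile 99.7). Leukocyte markers had a median of 0.08 over 8 measured genes (percentile 69.3).

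Of the 24 cholesterol and fatty acid synthesis genes measured with miR-195, 7 were at least 1.5-fold lower and none higher, with a median of -0.40. The sterol synthesis enzymes SQLE, FDFT1 and DHCR7 were at -0.66, -0.64 and -0.64. Genes of the microRNA machinery had a median of -0.37 over 13 members (percentile 0.05), with 4 lower by at least 1.5-fold: AGO2 (-0.92), the slicing Argonaute protein, the Dicer partner TARBP2 (-0.92), the Drosha partner DGCR8 (-0.79, with a second probe at -0.12) and MOV10 (-0.62). Apoptosis regulators had a median of 0.34 (percentile 99.9), with 7 of 22 higher and 2 lower by 1.5-fold. The higher members included pro-apoptotic BMF (1.76) and BCL2L11 (1.08, with its 4 probes between -0.11 and 1.08) and BAK1 (0.85), and the 2 lower ones were BIK (-1.13), also pro-apoptotic, and BCL2L2 (-0.70). Against the other 2 mimics this list was at 0.08 (percentile 65.6). TGF-beta responsive genes had a median of 0.29 over 21 members (percentile 99.6), with 7 higher by at least 1.5-fold, led by the matricellular protein CCN2 (3.07), PMEPA1 (1.13), TGFB2 (1.11) and the receptor TGFBR2 (0.99). The published targets of the miR-30 family were higher with miR-195, with a median of 0.22 over 29 genes (percentile 99.3), among them CCN2, DDIT4 (1.19), PRDM1 (0.86) and BNIP3L (0.77), whereas GALNT7 (-0.85) and VIM (-0.59) were lower.

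Over all genes that the naming rule admits, in lists or not, the largest decreases with miR-195 began with the secreted mucin-like MUCL1 (-2.67) and ARL2. The polyamine synthesis enzyme ODC1 (-1.80), CAB39L (-1.75), the phosphate transporter SLC20A2 (-1.70) and the glycosyltransferase B3GNT3 (-1.70) followed. Next came SH3BGRL2 (-1.69), the arginyl-tRNA synthetase RARS1 (-1.68), TPM3 (-1.66), MICB (-1.65), VTI1B (-1.61) and MRPL20 (-1.59). Probes of TPM3 ranged from -1.87 to -0.12 and those of MICB from -1.65 to -0.10. B3GNT3 was also lower with miR-30d (-1.56), and MUCL1 (-1.40), TPM3 (-1.28) and CAB39L (-1.08) with miR-182-3p. With miR-30d and miR-182-3p, RARS1 was at 0.20 and 0.21 and MICB at 0.08 and 0.75. The largest increases were in the ubiquitin-like UBD (3.69), the keratins KRT6C (3.37) and KRT6A (3.32), CCN2, the chemokine CX3CL1 (2.56), the aldo-keto reductase AKR1C1 (2.49), KRT80 (2.42), S100P (2.38), CEACAM1 (2.35), SERPINA3 (2.32), KLHL24 (2.30) and SLC16A6 (2.28). KRT6A and KRT6C are near-identical copies whose probes may not tell them apart, and a second CX3CL1 probe was at -0.22. The lowest probes of KRT80, CEACAM1 and SERPINA3 were at 0.67, 0.58 and 1.11 and the highest of SH3BGRL2 at -0.73. The Cy3 signal of SERPINA3 differed by -0.83 between the arrays. Of the 130 lower and 367 higher genes, 126 and 364 had the same sign against the mean of the other mimics, where the miR-195 array is the same. With Agilent's processed signals the counts were 278 lower and 618 higher.

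With miR-30d, published targets of the miR-30 family and mitotic genes were lower. Of 12776 genes, 74 were at least 2-fold lower and 74 higher. The 28 measured published targets had a median of -0.43, below all 10000 random lists, with 10 lower and 1 higher by at least 1.5-fold. The lowest were SEC23A (-1.98), a coat protein of vesicles that leave the endoplasmic reticulum, the mucin-type glycosyltransferase GALNT7 (-1.93), the mitophagy receptor BNIP3L (-1.44, with a second probe at -0.70), the G protein subunit GNAI2 (-1.42), the actin regulator TWF1 (-1.22), the phosphatase PTPN13 (-1.12), vimentin, VIM (-0.94), and the small GTPase RAP1B (-0.80). Mesenchymal markers, to which VIM belongs, were at -0.14 over 13 genes (percentile 4.58) and stood apart in 5 of 8 processing alternatives. These markers were at -0.34 (percentile 0.01) against the mean of the other 2 mimics, but at 0.085 (percentile 64.8) with a background fitted on all spots. The target that was higher was CCN2 (1.09). With miR-182-3p the same list was at -0.05 (percentile 33.0). In the reference channel it differed by -0.063 between the miR-30d and NC arrays.

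**Figure D2:**
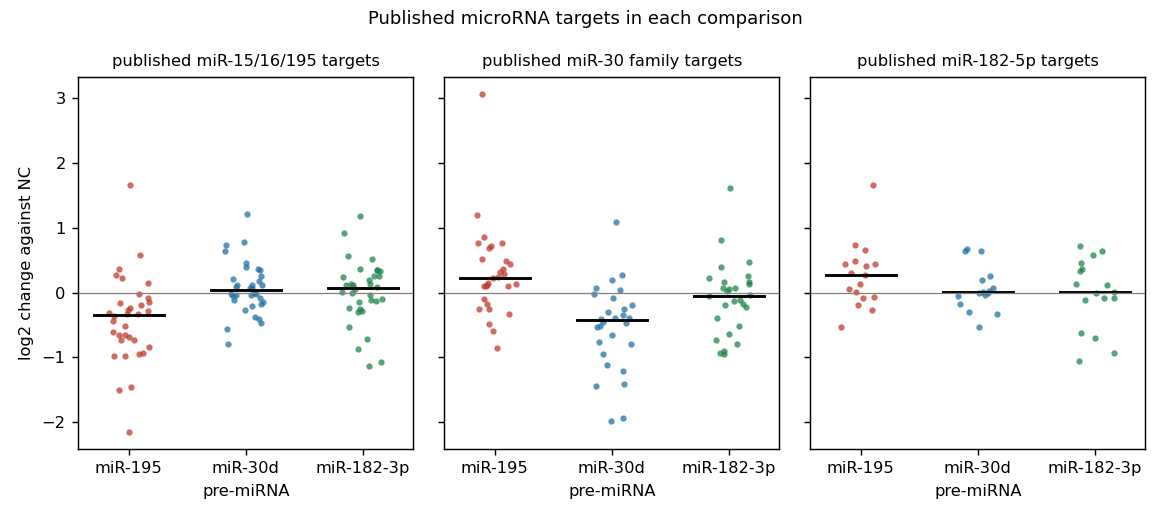
Log2 change against NC (vertical axis) of each measured gene in the published target lists of the miR-15, miR-16 and miR-195 family, the miR-30 family and miR-182-5p (panels), with each pre-miRNA (horizontal axis). Points are genes and black lines medians: -0.35 for the miR-195 family list with miR-195, -0.43 for the miR-30 list with miR-30d, and 0.015 for the miR-182-5p list with miR-182-3p.

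All 35 measured mitotic genes were below 0 with miR-30d, with a median of -0.43, and 7 were at least 1.5-fold lower, among them CCNB2 (-0.86), the kinetochore protein NUF2 (-0.82), HMMR (-0.81) and ANLN (-0.79). Against the mean of the other 2 mimics the list was at -0.26, below all random lists. The DNA replication list was at -0.09 (percentile 3.08) and did not stand apart, though it did in 6 of 8 processing alternatives, and RRM2, the small subunit of ribonucleotide reductase, was at -1.98. The cyclin-dependent kinase inhibitor CDKN1A (p21) was at 1.97, while the list of p53 target genes to which it belongs had a median of 0.08 (percentile 82.9), or 0.32 (percentile 99.9) with a background fitted on all spots. It also stood apart in 1 of 8 processing alternatives, the Cy5 channel alone (0.14). The MAPK feedback and immediate early list had a median of -0.13 (percentile 2), with 1 of 23 genes lower and 1 higher by 1.5-fold. The lower gene was EGR1 (-0.98), followed by FOSL1 (-0.55), IER2 (-0.41) and EREG (-0.37). The list no longer stood apart against the mean of the other 2 mimics (-0.11, percentile 6.1), without background subtraction (-0.11) or with a background fitted on all spots (-0.09, percentile 3.41), where EGR1 was at 0.04.

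TGF-beta responsive genes had a median of 0.23 over 20 genes with miR-30d (percentile 99.9), but only CCN2 was at least 1.5-fold higher. SMAD7 (0.46), BAMBI (0.46) and TGFB2 (0.44) came next. Targets of NRF2, the regulator of the antioxidant response, had a median of 0.22 over 18 genes (percentile 99.96), with 4 higher and 1 lower by 1.5-fold: AKR1C1 (2.01), the haem oxygenase HMOX1 (1.78), AKR1C3 (1.16) and GCLM (0.62). The AKR1C genes are close copies, so their probes may share signal. Neither list stood apart from the other 2 mimics, where the medians were -0.01 (percentile 46.4) and -0.03 (percentile 21.0). The microRNA machinery list was at -0.16 (percentile 1.76) with no member at 1.5-fold. Its lowest members were MOV10 (-0.47), AGO2 (-0.43), AGO1 (-0.39, with a second probe at -0.04) and TNRC6A (-0.39, with a second probe at 0.01). It stood apart in only 2 of 8 processing alternatives and was at 0.11 against the other mimics.

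The largest decreases with miR-30d were in the protease gene GZMB (-2.06), SEC23A, RRM2, the isocitrate dehydrogenase IDH1 (-1.96), GALNT7, B3GNT5 (-1.89), the adaptor subunit AP3S1 (-1.84), the metalloprotease ADAM19 (-1.84), the lipid kinase PIP4K2A (-1.84), CD99 (-1.82), PHTF2 (-1.82, with its 3 probes between -1.82 and -0.15) and PEG10 (-1.70). The largest increases were in PRSS35 (2.25), CDKN1A, the matrix protein MATN2 (1.74), the Wnt inhibitor APCDD1 (1.68), ANKRD46 (1.65), the monoamine oxidase MAOB (1.57), CHPF (1.55), DDIT4L (1.5), HOXB13 (1.49, with a second probe at 0.51), FGFBP1 (1.45), the sulfatase SULF2 (1.45) and MMADHC (1.44). Of the 74 lower and 74 higher genes, 73 and 53 had the same sign against the mean of the other mimics, where the miR-30d array is the same. When all spots entered the background estimate, the counts with miR-30d were 123 lower and 450 higher. These were more in all than with either other mimic under that fit (130 and 366 with miR-195, 344 and 170 with miR-182-3p). The lower share of calls with miR-30d was then 21.5% in place of an even split. In that fit PRSS35 was at 1.09, APCDD1 at 0.82, MAOB at 0.46, PEG10 at -1.06 and GZMB at -3.08. Agilent's processed signals gave 192 lower and 190 higher.

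With miR-182-3p, cholesterol synthesis genes and several epithelial genes were higher, DNA replication genes were lower, and lower genes outnumbered higher ones. Of 12815 genes, 355 were at least 2-fold lower and 169 higher, so that 67.8% of the calls were lower. The sterol list was the most displaced: 14 of 25 cholesterol and fatty acid synthesis genes were at least 1.5-fold higher and 1 was lower, with a median of 0.61, above all 10000 random lists. HMGCS1, which makes HMG-CoA, was at 1.76, the sterol sensor partner INSIG1 at 1.42, the mevalonate kinase MVK at 1.18 and MSMO1 at 1.08. SQLE was the member that was lower (-1.02). Against the mean of the other 2 mimics the list was at 0.80.

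Epithelial markers had a median of 0.32 over 17 genes with miR-182-3p (percentile 99.9), 6 of them higher and 1 lower by at least 1.5-fold. The adhesion molecule EPCAM was at 2.06, E-cadherin, CDH1, at 1.63, and the tight junction genes CLDN3 and OCLN at 1.57 and 0.77 (a second CLDN3 probe was at 0.66), whereas the tight junction gene TJP1 was at -1.24. Mesenchymal markers had a median of -0.21 over 16 genes (percentile 2.29), 4 lower and 1 higher by 1.5-fold. TWIST1 was at -0.74 (a second probe at -0.26), ITGA5 at -0.70, ZEB1 at -0.65 and TGFBI at -0.61, whereas AXL was at 1.6. The mesenchymal list stood apart in 5 of 8 processing alternatives. Set directly against miR-182-3p, the epithelial list was lower with miR-195 (a median difference of -0.26, percentile 1.3) and with miR-30d (-0.20, percentile 2.46). The epithelial list was at 0.02 (percentile 65.2) against the mean of the other 2 mimics, and the mesenchymal list at -0.25 (percentile 6.59).

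The 33 DNA replication genes had a median of -0.25 with miR-182-3p (percentile 0.35), with 7 lower by at least 1.5-fold and none higher. GINS3, a subunit of the replicative helicase, was at -2.10 (a second probe at -1.12), the clamp loader subunit RFC5 at -0.96 and RRM2 at -0.82. The list was at -0.20 (percentile 2.71) against the mean of the other 2 mimics and no longer stood apart. The G1/S list was at -0.22 (percentile 2.48), with 6 of 23 lower by 1.5-fold, including E2F2 (-1.16, with a second probe at -0.02), E2F3 (-1.07), E2F1 (-0.96) and CDKN2C (-0.91). It stood apart in 6 of 8 processing alternatives and was at -0.03 against the other mimics. Mitotic genes had a median of 0.06 (percentile 85.3). NRF2 targets had a median of 0.34 over 18 genes, above all random lists, with 7 higher and 1 lower by 1.5-fold, led by HMOX1 (1.90), AKR1C1 (1.83), AKR1C3 (1.29) and the cystine transporter SLC7A11 (1.17). Against the other mimics it was at 0.04 (percentile 70.3). The NF-kB list was at 0.25 (percentile 99.3), with 5 of 15 higher and 1 lower by 1.5-fold, including CCL20 (2.40), CXCL8 (1.16), CXCL1 (0.94) and LTB (0.76). It stood apart in 7 of 8 processing alternatives. Against the mean of the other mimics, which contains miR-195, it was at -0.23. Set directly against miR-182-3p, the NF-kB list was higher with miR-195 (a median difference of 0.78) and lower with miR-30d (-0.36, percentile 0.07). Hypoxia and glycolysis genes had a median of 0.19 (percentile 99.6) with 3 of 26 higher and 3 lower by 1.5-fold. EGLN3 (0.90), ALDOC (0.73), ENO2 (0.66) and PFKFB4 (0.57) were the highest, and ANKRD37 (-0.81), HK2 (-0.78) and DDIT4 (-0.74) the lowest.

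The published targets of the sister strand miR-182-5p served as a comparator for miR-182-3p, for which no target list was fixed. They had a median of 0.015 over 17 genes (percentile 51.6), with 4 lower and 2 higher by 1.5-fold. FBXW7 (-1.05), BDNF (-0.94, with a second probe at -0.36), MTSS1 (-0.70) and FOXO1 (-0.63, with a second probe at -0.43) were the lowest. RECK (-0.11), ADCY6 (-0.08), CREB1 (-0.08) and THBS1 (-0.00072) followed. The largest decreases with miR-182-3p were in the vesicle SNARE VAMP3 (-2.82), the histone methyltransferase subunit DPY30 (-2.66), the ciliary gene TCTN3 (-2.66), the RNA polymerase subunit POLR2L (-2.62), LSM14B (-2.35), the prolyl isomerase PPIL1 (-2.31), TMEM154 (-2.31), PXMP2 (-2.31), RRBP1 (-2.22), PIGT (-2.16), the iron-sulfur scaffold ISCU (-2.15) and POLD4 (-2.12). The largest increases were in the acid phosphatase ACP5 (2.61), CCL20, RAB11FIP4 (2.39, with a second probe at 0.41), KDF1 (2.38), EPCAM, KRT80 (2.06, with a second probe at 0.32), the epithelial transcription factor OVOL2 (2.05), FGFBP1 (2.01), ELOVL4 (1.98), ZNF165 (1.96), HMOX1 and FUT1 (1.82). Of the 355 lower and 169 higher genes, 351 and 156 had the same sign against the mean of the other mimics, where the miR-182-3p array is the same. Agilent's processed signals gave 517 lower and 416 higher, so that the lower share was 55.4%.

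**Figure D3:**
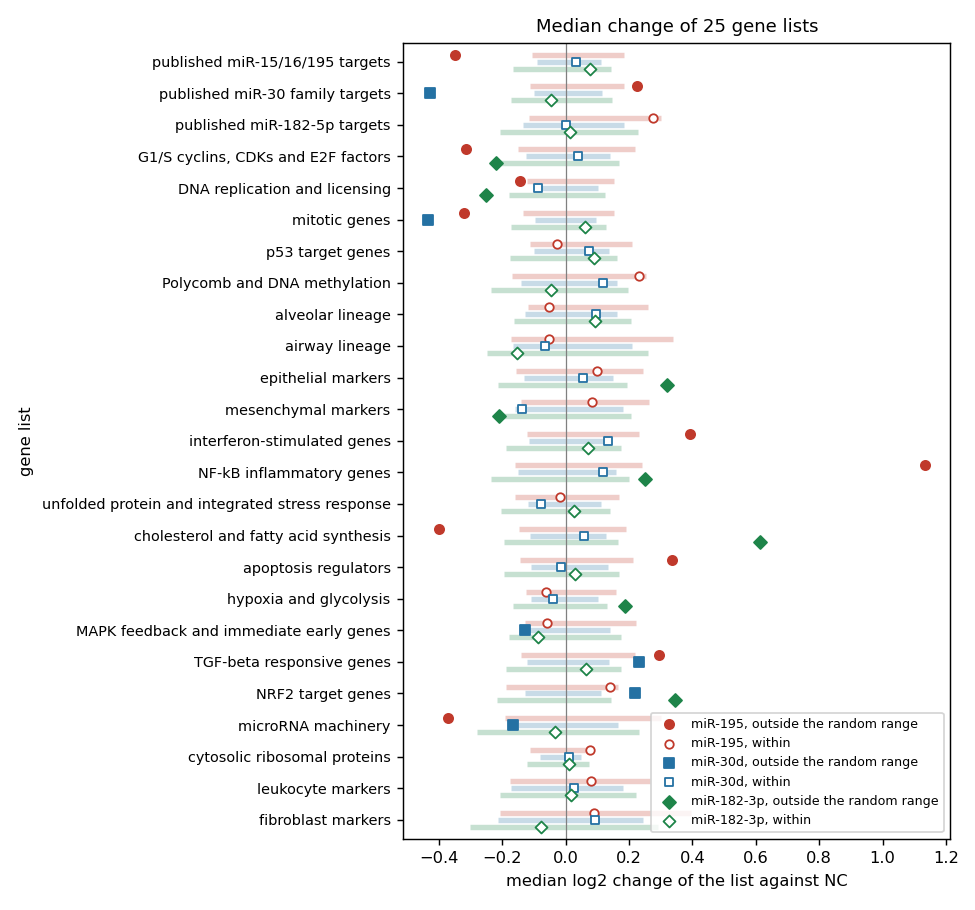
Median log2 change against NC (horizontal axis) of 25 gene lists (vertical axis) with miR-195 (red circles), miR-30d (blue squares) and miR-182-3p (green diamonds). Filled symbols lie in the outermost 2.5% at either end of 10000 random lists of matched expression, whose remaining range is shown as pale bars, and open symbols lie within that range. The NF-kB list with miR-195 has the highest median, 1.13, and the cholesterol list lies at -0.40 with miR-195 and 0.61 with miR-182-3p.

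Of the 25 lists, 11 stood apart with miR-195, 6 with miR-30d and 8 with miR-182-3p. The remaining lists did not stand apart from NC with any mimic, and their medians are given for miR-195, miR-30d and miR-182-3p in turn. The published miR-182-5p targets were at 0.28 (percentile 95.8), 0.0011 and 0.015. With miR-195 these targets stayed within the random range in 7 of 8 processing alternatives. The p53 targets were at -0.03, 0.08 and 0.09, and Polycomb and DNA methylation genes at 0.23, 0.12 and -0.05. Alveolar lineage genes were at -0.05, 0.09 and 0.09, and airway lineage genes at -0.05, -0.06 and -0.15. Genes of the unfolded protein and integrated stress response were at -0.02, -0.08 and 0.02, and cytosolic ribosomal protein genes at 0.08, 0.01 and 0.01. Leukocyte markers were at 0.08, 0.03 and 0.02, and fibroblast markers, with 6 measured genes, at 0.09, 0.09 and -0.08. Some of these lists did stand apart in other settings: p53 targets with miR-195 against the other mimics (-0.15, percentile 0.64) and with miR-30d as given above, alveolar genes with miR-30d in the fit on all spots (0.32, percentile 98), and ribosomal protein genes with miR-195 in Agilent's processed signals (0.13). NKX2-1, the lineage transcription factor of the lung, was at -0.08, -0.03 and 0.04, but at 1.25 with miR-30d when the background was fitted on all spots. EZH2, the Polycomb methyltransferase, was at -0.09, -0.09 and -0.39.

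Set directly against each other, the mimics differed in some lists, though not in the same ones for every pair. Between miR-195 and miR-182-3p, 275 genes were at least 2-fold lower and 860 higher with miR-195. The cholesterol list lay 0.99 log2 units lower with miR-195 (a median difference of -0.99, 18 of 24 genes at least 1.5-fold lower), and mitotic genes lay at -0.43 in the same direction. Between miR-195 and miR-30d, 138 genes were lower and 308 higher with miR-195. The published miR-30 targets differed by 0.85, with 16 of 28 genes at least 1.5-fold higher with miR-195, the published targets of the miR-195 family by -0.42, the NF-kB list by 1.22 and mesenchymal markers by 0.51 (percentile 100), whereas mitotic genes did not differ by the rule (0.08, percentile 84.4). Between miR-30d and miR-182-3p, 193 genes were lower and 428 higher with miR-30d, and mitotic genes differed by -0.45 and cholesterol genes by -0.64.

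The 3 comparisons share the NC array, which alone makes their changes correlate. Across 12640 genes, which are not independent replicates, the changes with miR-195 and miR-30d had r = 0.46, those with miR-195 and miR-182-3p r = 0.15, and those with miR-30d and miR-182-3p r = 0.26. Simulated unchanged mimics, given only the technical spread of the Cy3 channel (an SD of 0.074 per array), gave r = 0.50 in each pair. Equal noise on every array gives that value whatever its size, so it is no test. The covariances were 0.065, 0.030 and 0.038 against simulated values of 0.0055, 0.0055 and 0.0055. Genes at least 2-fold higher with a pair of mimics numbered 39, 36 and 28 in the same order, where independent lists would share 2.13, 4.77 and 0.97 and the simulation gave 0. Genes at least 2-fold lower numbered 6, 18 and 11, where independent lists would share 0.76, 3.64 and 2.07. The simulation leaves out the noise of the Cy5 channel and variation between cultures, so its small SD fixed its covariances and its overlap of 0. The independent lists leave out the shared control. Neither therefore gives the overlap expected by chance. Part of the excess may come from the shared control, which is a single array and could not be split.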

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

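Leaving spots of non-uniform background out of the main setting was chosen after seeing the data. The design fixed beforehand named no such exclusion, so the fit of the background on all spots lies closest to it. All other alternatives were planned. Of the repeated counts of genes and of lists, 71 stayed within 1.5 times the main count and 25 did not. Of the repeated values of named genes, 1381 stayed within the SD of the Cy3 channel and 417 moved further, and among those at least 1.5-fold in the main setting 11 changed sign. Smaller changes, such as NKX2-1 with miR-30d (1.25 in the fit on all spots), that changed sign are not in the 11. Genes named for the largest decreases and increases had to keep their sign under the background and normalisation alternatives and against the other mimics. They could not change sign there, so the 11 is partly set by the naming rule. No paired analysis was possible because each group has 1 array and no test was made. The planned search for 3' untranslated seed sites was not run. The cause of the changes below was not tested, except that a lower threshold admits more genes by construction and that the added offset of 50 compresses ratios in the main setting.

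Agilent's processed signals gave 278 lower and 618 higher genes with miR-195, 192 and 190 with miR-30d, and 416 higher with miR-182-3p. The deposited value table gave 279 and 619, 191 and 191, and 416. At 1.5-fold the counts were 608 and 1330 with miR-195, 439 and 439 with miR-30d, and 1186 and 755 with miR-182-3p. With the Cy5 channel alone, 119 genes were lower with miR-30d. Against the mean of the other 2 mimics, 127 were lower with miR-30d and 540 with miR-182-3p. With the background fitted on all spots, miR-30d had 123 lower and 450 higher genes. Epithelial markers were then at 0.35 (percentile 99.97) and interferon-stimulated genes at 0.28 (percentile 99.63) with miR-30d, and both stood apart. Lists that stood apart numbered 10 with miR-30d and 5 with miR-182-3p against the other mimics, 10 with miR-30d after the fit on all spots, and 5 with miR-182-3p without the filter on dim probes.

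Against the mean of the other 2 mimics, the medians of these lists changed sign, counting lists that stood apart from either control. With miR-195 the DNA replication list was at 0.027. With miR-30d the DNA replication list was at 0.13, epithelial markers at -0.18, interferon-stimulated genes at -0.19, NF-kB genes at -0.61, TGF-beta responsive genes at -0.010, NRF2 targets at -0.034 and microRNA machinery at 0.11. With miR-182-3p NF-kB genes were at -0.23 and TGF-beta responsive genes at -0.29. In the same comparison RRM2 was at 0.74 and BAK1 at -0.40 with miR-195, CCN2 at -1.24, AKR1C1 at -0.15, HMOX1 at -0.15 and AKR1C3 at -0.14 with miR-30d, and RRM2 at 0.50, CXCL1 at -0.056, LTB at -0.34 and AKR1C1 at -0.42 with miR-182-3p. EGR1 with miR-30d was at 0.043 when the background was fitted on all spots. Both own-target lists, the NF-kB and interferon lists with miR-195, the cholesterol lists with miR-195 and miR-182-3p, and the mitotic lists with miR-195 and miR-30d stood apart on the same side under each of the 9 alternatives fixed before the data were examined. These alternatives reuse the same arrays, so they are no independent check of a mimic's effect. Between 70.1% and 72.0% of spots were well above background in Cy5, and genes below that level have only bounds.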

Other observations

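The tests on the 3 patterns below were all chosen after the results were seen. Some genes were well above background on 1 side only. CASP1, which processes interleukin precursors, was at least 4.14-fold higher with miR-195 than with NC, and the tight junction gene CLDN1 at least 3.43-fold higher. DKK4, a secreted Wnt inhibitor, was at least 3.21-fold lower with miR-195 and at least 3.02-fold lower with miR-30d. These genes were picked after their values were seen, among 26 higher and 16 lower genes with a bound of at least 2-fold with miR-195 and 15 and 13 with miR-30d.

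Some genes, again picked after their values were seen, lay on opposite sides of NC with different mimics. CCND3 was at -0.98 with miR-195, 0.74 with miR-30d and 0.57 with miR-182-3p, and BNIP3L at 0.77, -1.44 and -0.39. APCDD1 was at 0.99 with miR-195, 1.68 with miR-30d and -1.77 with miR-182-3p. FGFBP1 was at -0.63, 1.45 and 2.01. DHCR7 was at -0.64, 0.22 and 1.01, and MVK at -0.60, 0.04 and 1.18. Opposite 2-fold calls numbered 9 between miR-195 and miR-182-3p, 4 between miR-30d and miR-182-3p and 0 between miR-195 and miR-30d.

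A set of 16 genes was at least 2-fold higher with all 3 mimics, among them AKR1C1, AKR1C3, AXL, CCN2, HMOX1, KRT6A, KRT6C, KRT80, MYO5C, RAB11FIP4, RARRES2, RILPL2, RPS25, SNPH and TNNI3. In the Cy5 channel alone 13 of them were still at least 2-fold higher with all 3 mimics, and their median Cy3 signal on the NC array was 0.054 log2 units above the mimics, which argues against the reference signal of the NC array as the whole cause; AKR1C3 and SNPH were below 2-fold there with each mimic, and RPS25 with miR-195 only. The 3 mimic arrays spanned a median of 0.64 log2 units for these genes, against a median of 1.25 between NC and the nearest mimic. The selection of the genes at 2-fold sets a floor on the latter distance, so this comparison decides nothing. A departure of the single NC culture, or of its Cy5 labelling, and a response common to the mimics cannot be told apart, because there is 1 NC array. FGF20, FGL2 and FHOD3 were at least 2-fold lower with all 3 mimics.

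The NF-kB inflammatory genes were higher with miR-195, with a median of 1.13. The median Cy3 difference of the list was -0.057, so the reference signal accounts for little of it. Leukocyte markers had a median of 0.079 with an SD of 0.34 over 8 genes and a highest value of 0.75 (CD8A), with CD68 at 0.27 and LYZ at 0.64, which argues against leukocyte RNA as the cause, as does the use of a cell line. NC was also a transfected precursor, so a response equal for every precursor would cancel against NC and could not give this rise. The list differed by 1.2176 between miR-195 and miR-30d and by 0.78 between miR-195 and miR-182-3p, both above all random lists. The rise was thus larger with miR-195 than with either other mimic. The list also stood apart as higher with miR-182-3p (0.25, percentile 99.3, 5 of 15 genes higher), so a smaller shared part stays open. An effect of miR-195 itself remains a hypothesis, and a difference between single cultures, in the amount of precursor taken up for example, was not tested.

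More genes were lower than higher with miR-182-3p. The lowest ratio of lower to higher genes over 5 background and normalisation alternatives was 1.243, against 2.10 in the main setting, so normalisation could set part of the asymmetry but did not remove it. Activity of the sister strand miR-182-5p was not decided: its published targets lay at percentile 51.55, with 4 lower and 2 higher by 1.5-fold, and targets found in other cells need not respond in SK-LC-7. An effect of miR-182-3p on its own targets was not tested, since no seed sites were searched.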
